A study of Danio rerio with 24 samples.

How the data were processed

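The samples were whole zebrafish embryos at dome, 80% epiboly, 24hpf and 48hpf, each immunoprecipitated for H3K4me3, H3K4me1 or H3K27ac, with 1 library per mark and stage. Per the labels, both H3K4 antibodies came from Diagenode and the H3K27ac antibody from Abcam, and library fragments were size-selected and amplified by PCR before sequencing. Of the 24 samples, 12 are labelled danRer6 and came with mapped reads and a peak list each, and 12 are labelled danRer7 and came with mapped reads only. No control library was analysed here.

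Read files as deposited list the start and end of every mapped read, and peak files as deposited list the start and end of every peak, with no score, height or probability. The danRer7 samples name CASAVA 1.8.2 and the build Zv9 in the submitters' processing notes. The aligner of the danRer6 reads, the peak caller and its threshold are not given in the sources used here, and neither is the meaning of the 0 and 1 in the columns after the read's end of the read files, which were not used. Per the file headers, the 4 files with 35-bp reads carry flow cell and lane names and the peak lists are named by mark and stage, so peaks were taken as called per library. Whether repeated reads were removed was read from the files themselves: those 4 files hold no repeated position, and their danRer7 counterparts hold 41.3% to 52.7% repeats.

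Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and figures were drawn with matplotlib 3.10.9. Reads on the mitochondrial genome were left out of library totals, and so were 6 H3K4me3 and 7 H3K4me1 peaks of dome that lie on it. Each read was placed at its 5′ end moved 100 bp in the direction of the read and counted in a region that holds this point. Levels are in RPM, the usual unit of read counts scaled to library size, computed here from nuclear reads. Depth was 4682378 to 9633775 danRer6 reads and 6945230 to 18758266 danRer7 reads per library.

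Peaks of different stages were called overlapping when they shared at least 1 bp. Peaks of the 4 stages of a mark were merged where they overlapped to give the regions of that mark. A peak was called distal when it lay more than 1 kb from every H3K4me3 peak of any stage, which stands in for the distance from a promoter because no gene annotation of danRer6 or danRer7 was used. Shares carry exact 95% Clopper-Pearson intervals, ratios of counts exact conditional binomial intervals, and both cover counting error only, since PCR reads are not independent molecules. Each share of overlap was set beside 100 random placements of the peaks on their own sequences, kept only where they met the criteria of the peaks they stand for.

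Changes in level between stages were taken as log2 of the ratio of RPM + 0.5 over merged regions with at least 20 reads summed over the 4 libraries of the mark, and counted when at least 4-fold. The counts given by random splits of 1 library into equal parts stand beside them as counting noise. They count differences in both directions together, between parts that each hold fewer reads than the library. Fold changes of named regions are ratios of RPM without the added 0.5, and where a count was 0, a lower bound against 3 reads. Windows of 500 bp were called enriched when their distinct reads, thinned to the smallest library of the mark, had a Poisson probability under 1e-05 against the larger of the genome mean and the 10 kb around them. Levels over surroundings are the read density within 500 bp of region midpoints divided by that 5 to 10 kb away, with 95% intervals from 200 bootstrap draws over regions. These bootstrap intervals hold no spread between libraries. H3K27ac domains are distal H3K27ac peaks joined within 12 kb. For stages taken in pairs, regions merged over all marks and stages with at least 20 distinct reads were counted when the lower stage of a pair was at least 4-fold over the higher stage of the other.

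Named regions were picked by a rule fixed before the data were examined, as were the comparisons and most of the alternatives. For each mark and each of the 3 consecutive intervals, the rule takes the 2 placed regions with the largest rise and the 2 with the largest fall in log2 of RPM + 0.5 among regions with at least 200 reads, the widest peak of every stage, and the 2 domains with the most reads at each stage. It gave 36 entries of changed regions, 32 of them distinct. Coordinates are 1-based and in danRer6 unless danRer7 is named, and none were converted between builds. Lists of developmental genes fixed at the same time were not used, since they need an annotation of these builds.

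The steps were tested on simulated data. With 100 regions changed 8-fold and 100 changed 16-fold between dome and 48hpf among those with at least 200 reads, and counts drawn at the real means and library sizes, the 4-fold count recovered 99%, 97% and 98% of the 8-fold changes for H3K4me3 (24709 regions), H3K4me1 (96954) and H3K27ac (86509), and 100% of the 16-fold changes for each. It called 0, 28 and 12 unchanged regions. The overlap step recovered 99.1% and 98.8% of planted overlaps among the 40325 H3K27ac peaks of dome, with up to 20% and up to 60% of them chosen. Among 2949762 windows of uniform reads, the window step recovered 43.3% of places raised to 6 times the mean and 97.5% of those at 11 times, and called 4 others, so it counts strong enrichment only.

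Alternatives covered the peak threshold (by width), joined peaks, placed chromosomes only, the overlap that counts, the distal distance of 3 kb and the H3K4me3 peaks behind it, lists of equal length, enriched windows, pseudocounts of 0.1 and 2 RPM, other read minimums, a 2-fold limit, scaling to regions with a peak at all 4 stages, 1 read per position, and thinned reads.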

Results

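Histone marks were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole zebrafish embryos at 4 stages of development: dome (late blastula), 80% epiboly (gastrula), 24 hours post fertilization (24hpf) and 48hpf. The 3 marks were H3K4me3, which lies at promoters, H3K4me1, which lies at enhancers and beside promoters, and H3K27ac, which lies at active promoters and enhancers. There was 1 library per mark and stage, 12 in all, and no replicates, so no p-values are given and every difference below is between single libraries. Peak intervals and mapped reads in the genome build danRer6 were used for all comparisons between stages, and reads of the same marks and stages in danRer7 were used to check them.

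The H3K4me3 files held 7463928 danRer6 reads at dome, 9633775 at 80% epiboly, 7961928 at 24hpf and 8100002 at 48hpf. The H3K4me1 files held 7177771, 8588447, 4682378 and 5343816 reads in the same order of stages. The H3K27ac files held 5946398, 5897789, 5982109 and 6747131 reads. The read files were of 3 kinds, which cross the stages for both H3K4 marks. The H3K4me3 and H3K4me1 files of 80% epiboly and 24hpf held 35-bp reads with no repeated position, and the other 8 held 48-bp reads with repeated positions kept, 6.87% to 17.4% of reads. Of those 8, the 4 H3K27ac files and the H3K4me1 file of 48hpf held no mitochondrial reads, and the H3K4me3 files of dome and 48hpf and the H3K4me1 file of dome held some. The files without them also held fewer reads than their danRer7 counterparts, 0.769 times as many for H3K4me1 and 0.79 to 0.82 times for H3K27ac. The 48-bp files with mitochondrial reads held 0.979 to 0.984 times as many. H3K4me3 at dome and 48hpf therefore came from files of 1 kind, as did all 4 stages of H3K27ac, and H3K4me1 at dome and 48hpf did not.

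The first comparison asked how promoter-type H3K4me3 differed between pluripotent and differentiating embryos. H3K4me3 was the most stable of the 3 marks. Of the 19103 dome peaks, 73.1% still overlapped a peak at 48hpf (95% interval 72.5% to 73.8%), against a mean of 6.18% for random placements. Of the 25191 regions that held an H3K4me3 peak at any stage, 53.2% held 1 at all 4 stages (interval 52.6% to 53.8%) and 19.4% at 1 stage only. Consecutive stages shared still more: 89.8% of dome peaks overlapped a peak at 80% epiboly, 81.1% of those at 80% epiboly a peak at 24hpf, and 78.6% of those at 24hpf a peak at 48hpf. Intervals on shares are exact Clopper-Pearson intervals and, like the intervals on folds, cover counting error only.

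The number of H3K4me3 peaks went from 19103 at dome to 22095 at 80% epiboly, 21498 at 24hpf and 16094 at 48hpf, a ratio of 0.843 between 48hpf and dome (interval 0.825 to 0.860). They covered 47.4, 31.5, 28.8 and 40.6 Mb, with median widths of 2279, 1273, 1238 and 2408 bp. The narrow peaks at 80% epiboly and 24hpf were those of the 35-bp read files. Counted instead as 500-bp windows enriched over their surroundings at equal depth, H3K4me3 held 33141, 33930, 34064 and 30085 windows, a ratio of 0.908 between 48hpf and dome.

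**Figure D1:**
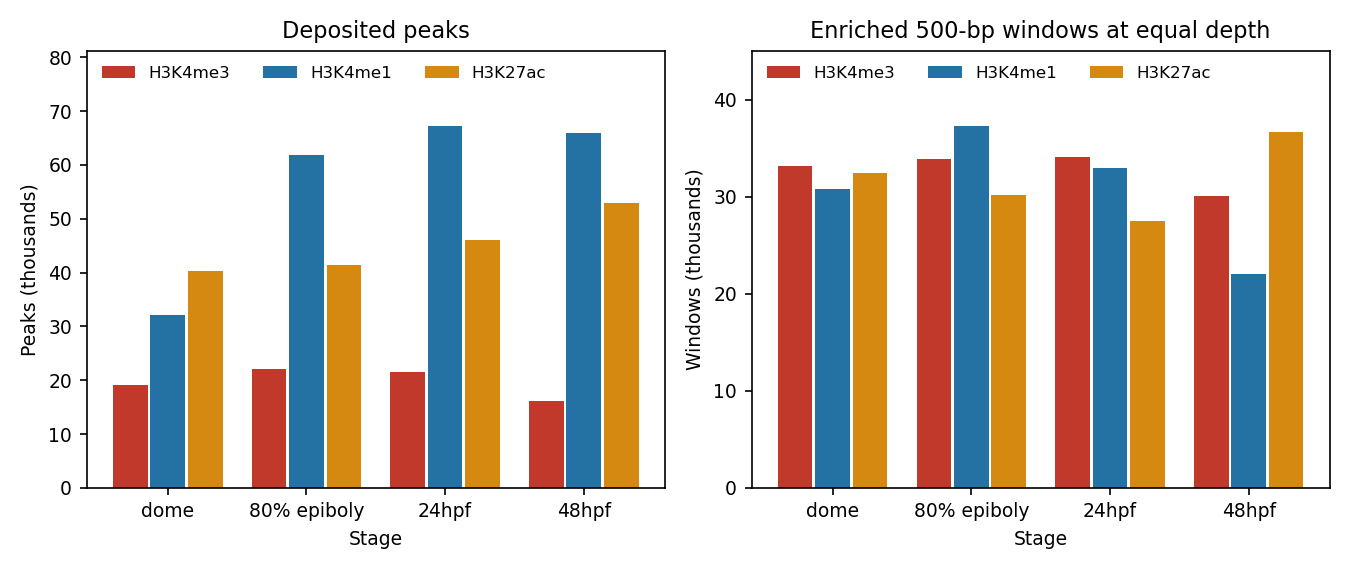
Number of deposited peaks (left) and of 500-bp windows enriched at equal read depth in danRer6 (right) by stage, 1 bar per library, coloured by mark. H3K4me1 went from 32198 to 65871 peaks between dome and 48hpf, while its enriched windows went from 30841 to 22084.

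Levels were compared as log2 of RPM + 0.5, where RPM is the usual unit of read counts scaled to library size, here to nuclear reads. Among 24836 H3K4me3 regions with at least 20 reads over the 4 libraries, 1252 were at least 4-fold higher at 48hpf than at dome and 2012 at least 4-fold lower. Random splits of 1 library into equal parts gave at most 37 such regions. Scaling to the median of the regions with a peak at all 4 stages gave 823 higher and 3323 lower, so regions that lost the mark outnumbered those that gained it under both scalings, but not with 2 RPM added in place of 0.5 (656 higher and 582 lower). Levels over these regions correlated with a Pearson r of 0.82 between dome and 48hpf and 0.95 between 24hpf and 48hpf, across regions within these libraries, which are not independent replicates. The interval from 80% epiboly to 24hpf, whose files were of 1 kind, had the most changes, with 1435 regions higher and 1016 lower at the later stage. From dome to 80% epiboly 880 were higher and 424 lower, and from 24hpf to 48hpf 105 were higher and 453 lower. These interval counts are not scaled. At regions with a peak at all 4 stages the median log2 change was 0.51, -0.002 and -0.51 from the first interval to the last. Reads inside the library's own peaks made up 54.8%, 76.5%, 75.8% and 54.7% from dome to 48hpf, more in the 35-bp files. The balance of the first and last intervals may therefore depend on scaling.

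Regions are given in danRer6, with levels in RPM. The largest H3K4me3 rises between 80% epiboly and 24hpf included a 10522-bp region on chromosome 16, 18979409 to 18989930, where H3K4me3 went from 3.94 to 269 RPM, 68.3-fold (interval 49.6 to 96.8). With 1 read per position, H3K27ac over the same region went from 18.0 to 160 RPM, while H3K4me1 went from 34.1 to 40.4 RPM. A region on chromosome 10, 6111678 to 6114648, fell from 51.4 to 0.502 RPM (102-fold, interval 39.7 to 377) and stayed at 0.494 RPM at 48hpf. On chromosome 12, 32252415 to 32257264, H3K4me3 was 38.5 RPM at dome and 54.0 RPM at 80% epiboly and then fell 71.6-fold (interval 32.7 to 196) to 0.754 RPM. H3K27ac over that region was 12.6 and 9.50 RPM at the first 2 stages and 0.363 RPM at 24hpf.

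The largest rises of H3K4me3 from 24hpf to 48hpf were smaller. A region on chromosome 2, 56730410 to 56734906, went from 2.89 to 37.7 RPM (13.0-fold, interval 8.53 to 20.9) and held a peak at 48hpf only. H3K27ac rose there too: the overlapping acetylated region, 56730236 to 56735098, went from 1.504 to 27.6 RPM (18.3-fold, interval 9.45 to 40.7), the largest H3K27ac rise of that interval among placed regions with at least 200 reads. H3K4me1 over it was 4.27 RPM at 24hpf and 6.77 RPM at 48hpf with 1 read per position. On chromosome 25, 7489444 to 7495085, H3K4me3 went from 4.52 to 50.99 RPM (11.3-fold, interval 8.01 to 16.3).

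Other H3K4me3 regions picked by the same rule included regions high in both 35-bp files and regions empty in 1 of them. A region on chromosome 3, 30075112 to 30077752, was at 2.01 RPM at dome, 331 at 80% epiboly, 425 at 24hpf and 1.73 at 48hpf, and H3K4me1 over it stood at 388 and 721 RPM at the same middle stages against 2.62 and 4.51 RPM at dome and 48hpf. H3K27ac over it was 3.04 RPM at 80% epiboly and 13.8 RPM at 24hpf. The 35-bp files hold 1 read per position, which capped the H3K4 levels here (3185 and 3384 H3K4me3 reads in 2641 bp). A region on chromosome 11, 43606968 to 43607584, went from 0.536 to 38.8 and 51.2 RPM and back to 0.988 RPM. A pair of regions on chromosome 23, 39801535 to 39803210 and 43552756 to 43554770, held no H3K4me3 or H3K4me1 read at 80% epiboly, with H3K27ac at 8.17 and 2.66 RPM. Their H3K4me3 at 24hpf, also from a 35-bp file, was 33.5 and 11.7 RPM, while H3K4me1 over the second was 0 at both 35-bp stages and 4.10 RPM at dome with 1 read per position. Against the limit of 3 reads that a count of 0 allows, their H3K4me3 was at least 41.7-fold and 28.8-fold lower at 80% epiboly than at dome. Since both H3K4 files of 80% epiboly were empty there, these bounds describe reads in the files. Whether the mark itself was lost was not tested.

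The second comparison asked how H3K4me1, the enhancer-associated mark, was laid down. H3K4me1 sites changed far more than H3K4me3 sites, and its gains lay mostly away from promoters. Of 105192 regions with an H3K4me1 peak at any stage, 14.9% had 1 at all 4 stages (interval 14.7% to 15.1%) and 49.1% at 1 stage only. Of the 32198 dome peaks, 53.9% overlapped a 48hpf peak (interval 53.4% to 54.5%), against 13.95% for random placements, although 89.3% overlapped a peak at 80% epiboly. The share of H3K4me1 peaks that were distal, more than 1 kb from every H3K4me3 peak of any stage, was 37.0% at dome, 56.0% at 80% epiboly, 61.7% at 24hpf and 71.1% at 48hpf. Wide peaks come within 1 kb of an H3K4me3 peak more easily, and the dome peaks were the widest and fewest. No distal share at equal width is given here, so part of this rise may follow the lists.

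The number of H3K4me1 peaks was 32198, 61770, 67271 and 65871 from dome to 48hpf, a ratio of 2.05 between 48hpf and dome (interval 2.02 to 2.07). Peaks narrowed at the same time, from a median of 2269 bp at dome to 1058, 811 and 649 bp, and the covered length fell from 82.3 to 78.1, 66.5 and 51.2 Mb. The ratio turned around when 500-bp windows enriched at equal depth were counted in place of peaks. Windows numbered 30841 at dome and 22084 at 48hpf, a ratio of 0.716, and the danRer7 reads gave 0.403. At the stages between they numbered 37311 and 32949, and the ratio of 24hpf to dome was 1.07. The danRer6 file of 48hpf held 0.769 times its danRer7 reads, against 0.979 times at dome. A broad site holds several windows: with adjoining windows joined, regions numbered 21255, 27447, 27075 and 19850 from dome to 48hpf. The turn thus goes with the unit and the calling rule, and was smaller for joined regions.

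Of 96253 H3K4me1 regions tested, 14298 were at least 4-fold higher at 48hpf than at dome and 5101 at least 4-fold lower. The regions that rose were 95.05% distal and those that fell 43.1% distal, against 73.4% of all regions tested. Random splits of 1 library gave 116 to 1315 such regions. Scaling to the regions with a peak at all 4 stages, where the median log2 change was -0.80, gave 30377 higher and 1925 lower, and the balance turned with at least 100 reads (2874 higher and 3270 lower) and with 2 RPM added (1073 and 1172). Within the pair of 35-bp files, 80% epiboly to 24hpf, 6101 regions were higher (94.1% distal) and 2922 lower (85.6% distal). The Pearson r across regions was 0.84 from dome to 80% epiboly, 0.66 from there to 24hpf, 0.67 from 24hpf to 48hpf and 0.44 from dome to 48hpf.

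Between 80% epiboly and 24hpf, the largest H3K4me1 rise was at a distal region on chromosome 13, 22383860 to 22387292, from 1.51 to 24.8 RPM (16.4-fold, interval 9.20 to 31.7). The acetylated region that contains it, 22383440 to 22388298, had 1 of the 2 largest H3K27ac rises of the same interval, from 2.88 to 49.8 RPM (17.3-fold, interval 10.6 to 30.1). A second distal region, on chromosome 18, 20112854 to 20115619, went from 1.98 to 27.8 RPM of H3K4me1 (14.0-fold, interval 8.43 to 24.8), with H3K27ac at 2.85 and then 12.7 RPM. H3K4me3 over both regions was at most 2.60 RPM at every stage with 1 read per position.

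Falls of H3K4me1 between the same stages were led by chromosome 2, 15373311 to 15376165, from 14.7 to 0.427 RPM (34.4-fold, interval 9.31 to 287), and by chromosome 1, 13320629 to 13322541, from 17.8 to 0.641 RPM (27.8-fold, interval 9.34 to 136). At the chromosome 2 region H3K27ac had already gone from 55.8 RPM at dome to 10.6 RPM at 80% epiboly, when H3K4me1 was still at 14.7 RPM. From dome to 80% epiboly, a distal region on chromosome 15, 37574615 to 37578548, lost H3K4me1 from 19.4 to 4.08 RPM (4.75-fold, interval 3.26 to 7.10) while H3K27ac there went from 42.7 to 3.42 RPM. A distal region on chromosome 18, 35724466 to 35728572, held 17.6 and 10.9 RPM of H3K4me1 at the first 2 stages, 1.07 RPM at 24hpf and 6.74 RPM at 48hpf. Repeated reads made up part of the change at a pair of the regions picked by the rule. The region of chromosome 23, 40885491 to 40887456, fell by 2.72 on the log2 scale from dome to 80% epiboly, or by 0.42 with 1 read per position. The region of chromosome 23, 6285390 to 6286916, rose from 22.2 to 125 RPM from 24hpf to 48hpf, with 64.1% of its reads at distinct positions, and from 22.2 to 70.4 RPM with 1 read per position. The remaining H3K4me1 regions picked were the chromosome 3 and 11 regions already described, in slightly wider form, and chromosome 23, 1726429 to 1727579, which went from 1.53 RPM at dome to 54.1 and 99.3 RPM at the 35-bp stages and 0.936 RPM at 48hpf.

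**Figure D2:**
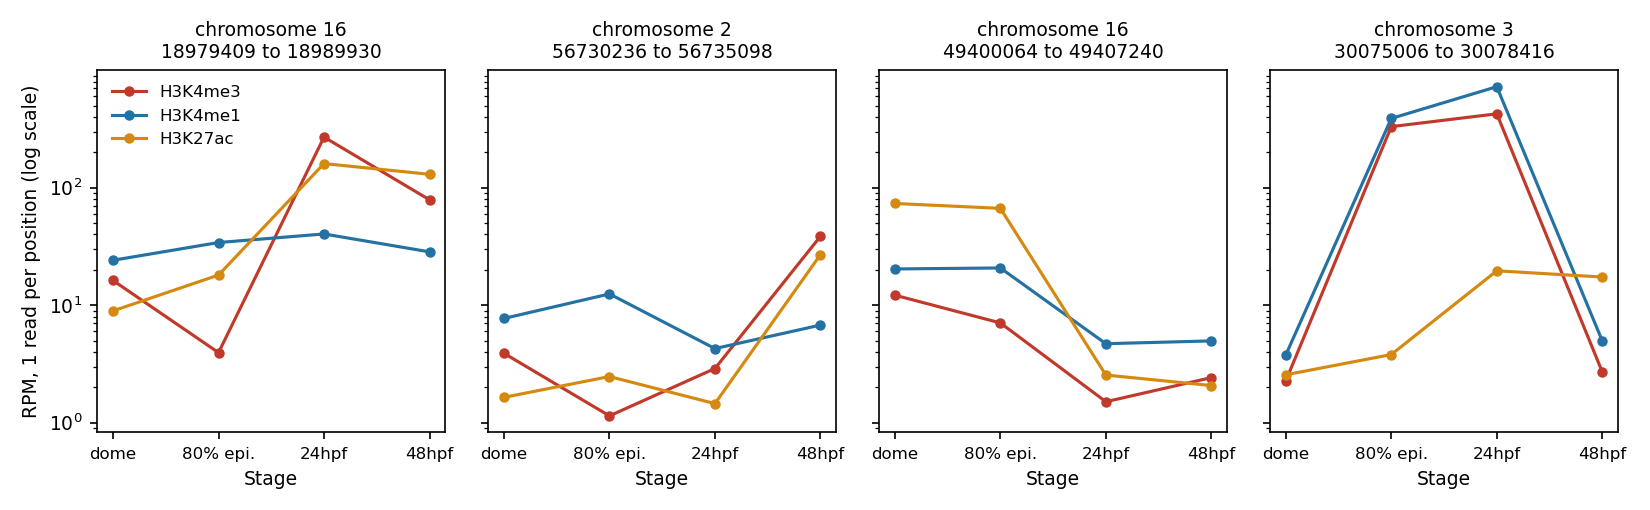
Levels of the 3 marks at 4 of the named regions (danRer6), in RPM with 1 read per position on a log scale, against stage; each point is 1 library. H3K4me3 on chromosome 16, 18979409 to 18989930, reached 269 RPM at 24hpf, and the chromosome 3 region stood at 331 to 723 RPM in both H3K4 marks at 80% epiboly and 24hpf only, levels capped by the limit of 1 read per position.

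The third comparison asked how H3K27ac, the mark of active elements, was redistributed. By peak lists, acetylated sites turned over about as much as H3K4me1 sites, but regions of enriched windows at equal depth kept 48.1% of H3K27ac and 29.1% of H3K4me1 from dome to 48hpf (46.7% and 19.9% in danRer7). Of 87381 regions with an H3K27ac peak at any stage, 16.6% had 1 at all 4 stages (interval 16.3% to 16.8%) and 47.4% at 1 stage only. Of the 40325 dome peaks, 48.7% overlapped a 48hpf peak (interval 48.2% to 49.2%), against 12.15% for random placements. Turnover ran through all 3 intervals: 61.2% of dome peaks overlapped a peak at 80% epiboly, 58.6% of the latter a peak at 24hpf, and 73.8% of those at 24hpf a peak at 48hpf. Distal sites gained and lost numbered 13790 and 12680 in the first interval, 18805 and 13573 in the second and 16116 and 10361 in the last.

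H3K27ac peaks numbered 40325 at dome, 41447 at 80% epiboly, 45978 at 24hpf and 52946 at 48hpf, a ratio of 1.31 (interval 1.30 to 1.33), and covered 68.9, 72.3, 78.1 and 88.4 Mb. Enriched windows at equal depth numbered 32447, 30197, 27467 and 36660, a ratio of 1.13 between 48hpf and dome, and so fell up to 24hpf where the peak numbers rose. Distal peaks made up 57.8%, 59.2%, 65.1% and 67.4% of them.

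**Figure D3:**
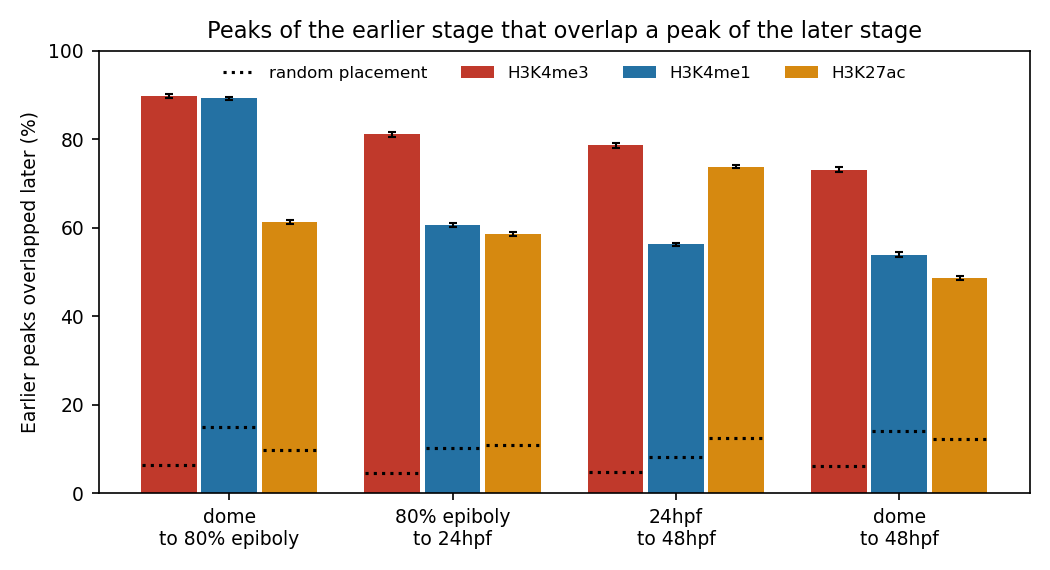
Share of the earlier stage's peaks that overlapped a peak of the later stage by at least 1 bp (percent), for the 3 consecutive intervals and for dome to 48hpf; bars are marks, error bars are exact 95% Clopper-Pearson intervals (counting error only) and dotted lines the mean of 100 random placements. H3K4me3 kept 73.1% of its dome peaks at 48hpf, H3K4me1 53.9% and H3K27ac 48.7%, against 73.3%, 29.1% and 48.1% for regions of enriched windows at equal depth.

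Of 86916 H3K27ac regions tested, 11181 were at least 4-fold higher at 48hpf than at dome and 8009 at least 4-fold lower, and random splits of 1 library gave 193 to 643. Of the regions that rose, 84.0% were distal, and of those that fell 72.2%, against 73.9% of all regions tested, while from 24hpf to 48hpf the shares were 68.6% and 87.4%. The last share rests on 246 regions. A random split of the 24hpf library gave 480, but in both directions together and between parts with fewer reads than the library. The 480 therefore does not measure the noise in the 246. From dome to 48hpf the scaled counts were 13538 higher and 6725 lower, and with 2 RPM added the balance turned to 2705 higher and 2983 lower. Level changes of at least 4-fold were fewer after 24hpf: 3028 regions rose and 2715 fell from dome to 80% epiboly, 3088 rose and 2296 fell from there to 24hpf, and 592 rose and 246 fell from 24hpf to 48hpf. These interval counts are not scaled, and their balance depends on scaling. At regions with a peak at all 4 stages the median log2 change was -0.083, -0.340 and 0.167 in the same order. The Pearson r across all regions tested was 0.74, 0.66 and 0.84 for the same intervals and 0.40 between dome and 48hpf.

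From dome to 80% epiboly, a distal region on chromosome 14, 42483962 to 42487500, gained H3K27ac from 1.01 to 34.6 RPM (34.3-fold, interval 15.5 to 94.5), and H3K4me1 over it went from 1.804 to 19.3 RPM. On chromosome 7, 51883271 to 51887533, H3K27ac went from 0.504 to 22.6 RPM (44.7-fold, interval 14.97 to 219.5) and stayed at 23.7 and 19.0 RPM at the later stages, with H3K4me1 at 3.94 and then 18.8 RPM. The sharpest losses after dome were on chromosome 6, 34089605 to 34093578, from 88.96 to 2.71 RPM (32.8-fold, 529 and 16 reads), and on chromosome 13, 37119764 to 37123130, from 57.7 to 2.04 RPM (28.4-fold, interval 16.02 to 55.4). H3K4me1 fell less at both: from 34.8 to 17.0 RPM and from 20.5 to 8.62 RPM.

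From 80% epiboly to 24hpf, H3K27ac on chromosome 3, 48420510 to 48423339, rose from 1.19 to 30.3 RPM (25.5-fold, interval 12.1 to 64.3), with H3K4me1 at 1.75 and then 13.5 RPM. It fell on chromosome 6, 41484995 to 41487416, from 24.6 to 0.334 RPM (73.5-fold, interval 19.99 to 613) and on chromosome 16, 49400064 to 49407240, from 72.2 to 2.34 RPM (30.9-fold, interval 18.2 to 56.9). At the chromosome 16 region H3K4me1 stood at 20.3 and 20.7 RPM at the first 2 stages and 4.70 RPM at 24hpf, and H3K4me3 at 12.2, 7.06 and 1.51 RPM. From 24hpf to 48hpf, chromosome 19, 9065631 to 9069428, rose from 4.18 to 53.4 RPM (12.8-fold, interval 8.51 to 19.99), and chromosome 3, 24390447 to 24394538, and chromosome 7, 39730508 to 39734860, fell from 18.7 RPM each to 3.26 and 3.41 RPM.

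The widest acetylated interval of the series was a 24hpf peak of 42757 bp on chromosome 23, 35117488 to 35160244, whose H3K27ac stood at 56.7, 233, 644 and 475 RPM from dome to 48hpf. At dome the widest was 34869 bp on chromosome 1, 43103825 to 43138693, at 653, 409, 273 and 297 RPM. The widest H3K27ac peak of 80% epiboly, 27186 bp, lay on chromosome 2, 31948578 to 31975763, and the widest of 48hpf (26390 bp) and the widest H3K4me1 peaks of 24hpf (22125 bp) and 48hpf (17170 bp) overlapped it. The widest H3K4me3 peak of dome, 28548 bp, lay on chromosome 25, 35596680 to 35625227, and that of 24hpf, 11488 bp, on chromosome 13, 5881018 to 5892505, where H3K4me3 went from 20.4 RPM at dome to 402 RPM at 24hpf.

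Distal H3K27ac peaks within 12 kb of each other were joined into domains and ranked by reads. Of the 500 domains with the most reads at dome, 42.0% overlapped 1 of the top 500 at 80% epiboly and 20.8% 1 of the top 500 at 48hpf, and 62.4% of the top 500 at 24hpf overlapped 1 at 48hpf. A domain can leave the top 500 and stay acetylated, and no random value was computed for these shares. The second domain of dome, on chromosome 3, 38918157 to 39086287, stood at 826.7, 744.5, 500.3 and 626 RPM. The domain with the most reads at both 80% epiboly and 24hpf was the same part of chromosome 13, 18747828 to 19088287 at 80% epiboly, 340.5 kb wide, at 477 RPM at dome and 1198, 1023 and 813 RPM after. The first domain of dome, 18592255 to 18732418, lay beside the domain of 80% epiboly and overlapped the start of that of 24hpf (18707865 to 19054772), and its level ran the other way, from 829.7 RPM to 326, 302 and 287 RPM. At 48hpf the first domain was on chromosome 5, 30856745 to 31008262, at 309, 663, 804 and 1229 RPM from dome to 48hpf.

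The fourth comparison asked how often H3K4me1 away from promoters went with H3K27ac, as at active enhancers, or stood without it. At every stage distal H3K4me1 peaks were split between both states. H3K27ac of the same stage covered 67.9% of the 11910 distal H3K4me1 peaks at dome (interval 67.0% to 68.7%), 47.8% of 34559 at 80% epiboly, 53.2% of 41514 at 24hpf and 50.1% of 46839 at 48hpf. Random placements gave 5.55% to 6.83%. The higher share at dome went with the shorter list of wider peaks there: when every list was limited to the widest peaks up to the length of the shortest list of its mark, the shares were 64.4%, 68.9%, 71.7% and 62.4%. With enriched windows at equal depth they were 46.0%, 32.4%, 26.4% and 35.1%.

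Seen from H3K27ac, 38.2% of distal acetylated peaks held an H3K4me1 peak at dome (interval 37.6% to 38.9%), and 61.7%, 63.7% and 58.2% at the later stages. Promoter-type regions carried all 3 marks to differing degrees. H3K27ac overlapped 68.9% of H3K4me3 peaks at dome, 62.8% at 80% epiboly, 63.3% at 24hpf and 81.5% at 48hpf, while H3K4me1 overlapped 89.5%, 85.3%, 80.8% and 66.3%. Around H3K4me3 peak midpoints, H3K4me1 reads stood 8.16, 6.87, 6.65 and 4.21 times over the surroundings from dome to 48hpf, and H3K27ac reads 8.50, 8.54, 7.44 and 10.7 times.

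The fifth comparison asked in which order the enhancer marks arrived. Most distal sites that gained H3K27ac between stages had no H3K4me1 peak beforehand, and the share that did was larger at each later interval. It was 6.01% of the 13790 sites gained by 80% epiboly (interval 5.62% to 6.42%), 3008 of the 18805 gained by 24hpf (15.5% to 16.5%) and 30.98% of the 16116 gained by 48hpf (30.3% to 31.7%). Random placements gave 1.32%, 3.38% and 3.20%. At the stage of the gain itself, 50.5%, 55.1% and 45.4% of these sites held H3K4me1. Sites acetylated at both stages held H3K4me1 beforehand in 51.4%, 74.5% and 75.8%.

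The first step of this rise was not kept when the lists were of equal length, where the shares were 6.81%, 5.97% and 13.6%, and it was kept with enriched windows at equal depth, 5.10%, 9.13% and 19.4%. In all of these settings the share was highest for sites gained by 48hpf.

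**Figure D4:**
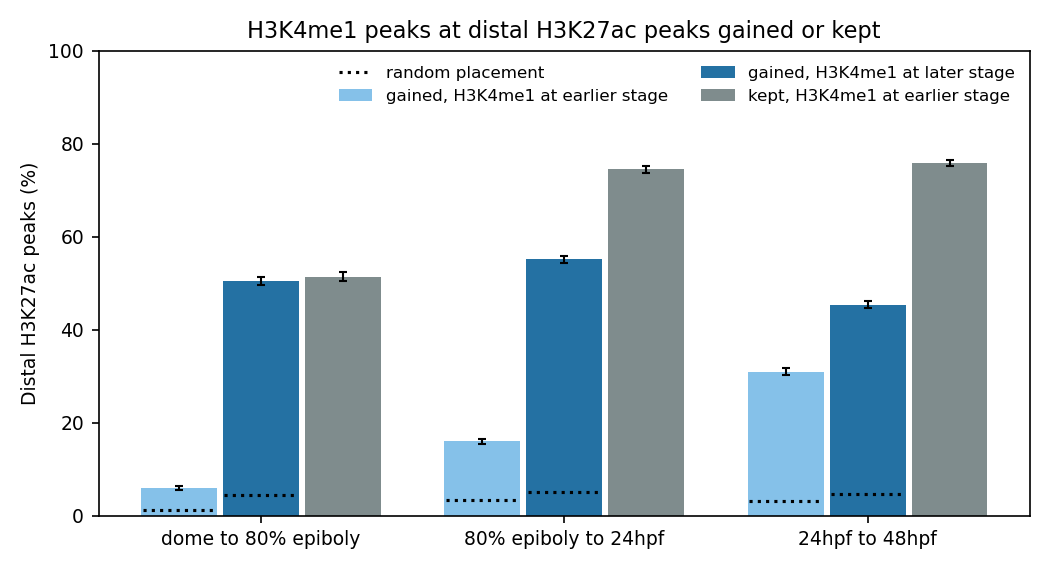
Share of distal H3K27ac peaks (percent) that overlapped an H3K4me1 peak, for peaks gained in each interval (H3K4me1 at the earlier and at the later stage) and for peaks kept through it (H3K4me1 at the earlier stage); error bars are exact 95% Clopper-Pearson intervals (counting error only) and dotted lines the mean of 100 random placements. The share with H3K4me1 before the gain was 6.01% for gains by 80% epiboly and 30.98% for gains by 48hpf.

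Read levels at the same sites, which were chosen by H3K27ac peaks, were compared too. At sites that gained H3K27ac by 80% epiboly, H3K4me1 density over the surroundings was 1.14 at dome and 2.06 at 80% epiboly. At sites gained by 24hpf it was 1.33 before and 2.499 after, and at sites gained by 48hpf it was 2.001 before and 2.48 after, with random distal places at 0.776 to 0.921. H3K4me1 stood above random places before the gain in all 3 intervals, most so in the last, but so did H3K27ac, at 1.26, 1.43 and 1.65 against 0.760 to 0.850 at random places. These levels do not show which mark arrived first.

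Distal sites that lost their H3K27ac peak were followed for H3K4me1. Of the 12680 sites lost between dome and 80% epiboly, 28.0% held an H3K4me1 peak before and 27.6% after, from a longer H3K4me1 list. H3K4me1 density at the sites lost in this interval was 1.61 (interval 1.58 to 1.64) at dome and 1.44 (1.42 to 1.48) at 80% epiboly. These intervals are over regions within 1 library each, and the files were of different kinds. Of the 13573 lost between 80% epiboly and 24hpf, 51.9% held 1 before and 24.1% after, and H3K4me1 density went from 2.15 to 1.59. Of the 10361 lost between 24hpf and 48hpf, 41.1% held 1 before and 28.4% after, with H3K4me1 density at 1.99 and 1.94. Sites acetylated at dome only kept some H3K4me1 throughout, at 1.58, 1.38, 1.147 and 1.46, and sites acetylated at 48hpf only went from 1.08 to 1.29, 1.99 and 2.501.

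**Figure D5:**
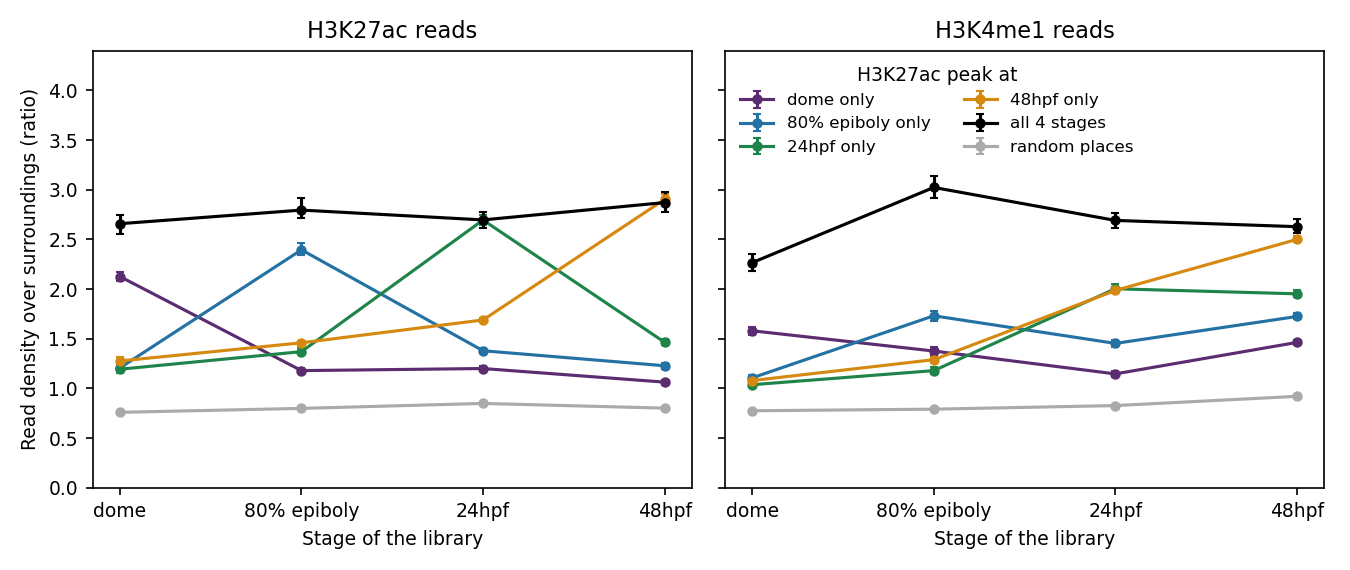
H3K27ac reads (left) and H3K4me1 reads (right) at distal H3K27ac regions, as read density within 500 bp of the midpoint over that 5 to 10 kb away (ratio), against the stage of the library; lines are regions with an H3K27ac peak at 1 stage only, at all 4 stages, or random distal places, and error bars are 95% bootstrap intervals over regions. The intervals hold no spread between libraries. At regions acetylated at 48hpf only, H3K4me1 was 1.08 at dome, 1.99 at 24hpf and 2.501 at 48hpf.

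The last comparison asked whether the danRer7 reads came from further embryos or were the same libraries mapped again. Runs of 3 successive gaps between read positions were matched between builds, since these are kept when the same reads are placed on another version of the sequence. Each library's own danRer7 file held 26.5% to 56.7% of its danRer6 gap runs, and no other library's file held more than 3.48%. On this ground the danRer7 files were treated as the same libraries and never as replicates. The share of reads per chromosome correlated with a median Pearson r of 0.98 over the 12 pairs (lowest 0.976), but no such value was computed between different libraries, so it does not tell them apart.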

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

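Mitochondrial reads entered no comparison of the report and are given here because they exceeded the limit that a count of 0 allows, and all tests of their source were chosen only after these values were seen. In danRer6, H3K4me3 held 79.2 RPM of mitochondrial reads (scaled to all reads) at dome, 1.38 at 24hpf and 5.80 at 48hpf, and H3K4me1 held 103 at dome, 0.699 at 80% epiboly and 4.70 at 24hpf. The peak lists of these dome libraries included 6 H3K4me3 and 7 H3K4me1 peaks on the mitochondrial genome. In danRer7, H3K4me3 held 1219, 10.7, 17.9 and 93.0 RPM of mitochondrial reads from dome to 48hpf, H3K4me1 held 1607, 76.3, 72.3 and 74.6, and H3K27ac held 13.5, 275, 244 and 17.4.

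Both H3K4 marks thus had far more mitochondrial reads at dome than at any later stage. Blastula cells inherit many mitochondria from the egg, so more mitochondrial DNA per nucleus was tried as a biological explanation. The H3K27ac library of dome had 13.5 RPM, the lowest of the 4 H3K27ac libraries in danRer7. But those libraries ranged from 13.5 to 275 RPM without following the order of stages, so 1 dome library cannot decide this explanation. Processing of this kind of read file was argued against by the H3K4me3 files of dome and 48hpf, which were of 1 kind and differed 13.1-fold. A larger background was argued against too, since the share of H3K4me3 reads outside peaks was 0.999 times as large at dome as at 48hpf. A step in the preparation of those dome libraries, such as how nuclei were separated, also stays open as a possible explanation and was not tested.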

How the results depend on the processing

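Alternatives gave 737 values for 110 results, of which 176 belong to the 23 results the report leads with. They moved these results beyond their counting intervals 116 times, reversed 1 of them under 2 settings and left 58 within the interval or, for counts, within 1.5 times. Among these results only the ratios of peak numbers could be counted as reversed. A change in the balance of higher and lower counts, given below, is not part of that tally. The windows as a stand-in for shares, the windows in danRer7, the lists without the middle stages, 24hpf in place of 48hpf, 1 read per position with thinning for the 4-fold counts, and 1 read per position for the chromosome shares of both builds were chosen after seeing the data. Unless the construction shows it, the cause was not tested.

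Enriched windows at equal depth reversed the ratio of H3K4me1 peaks at 48hpf over dome, to 0.716 in danRer6 and 0.403 in danRer7. For H3K4me3 the ratio was 0.908 and 0.909, and for H3K27ac 1.13 and 1.08. With 24hpf in place of 48hpf the H3K4me1 ratio was 2.09 from peaks and 1.07 from windows, and 71.3% of dome peaks were overlapped. Joining peaks within 1 kb gave ratios of 1.99 for H3K4me1 and 1.43 for H3K27ac.

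Counts of regions at least 4-fold changed from dome to 48hpf depended on the limit and the added RPM by construction. At 2-fold, 4216 H3K4me3 regions were higher and 6404 lower, 39648 and 20657 for H3K4me1, and 31598 and 20918 for H3K27ac. With at least 100 reads, 1261 H3K4me3 regions were lower, 2874 H3K4me1 regions higher and 3270 lower, and 5247 H3K27ac regions higher and 4027 lower. With 0.1 RPM added, 3315 H3K4me3 regions were lower, 25824 H3K4me1 regions higher and 8228 lower, and 17361 H3K27ac regions higher. With 2 RPM added, the counts were 656 and 582 for H3K4me3, 1073 and 1172 for H3K4me1, and 2705 and 2983 for H3K27ac. The larger of the higher and lower counts thus changed sides for all 3 marks with 2 RPM added, and for H3K4me1 with at least 100 reads, and both settings give regions with few reads less weight or none. It changed sides for H3K4me1 also over merged enriched windows in danRer7, with 3515 higher and 5821 lower, but not in danRer6 (5834 and 4437). Scaled to regions with a peak at all 4 stages, they were 823 and 3323 for H3K4me3 and 30377 and 1925 for H3K4me1.

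The share of dome peaks overlapped at 48hpf, in the order H3K4me3, H3K4me1 and H3K27ac, was 71.9%, 13.1% and 45.0% where at least 50% of the peak had to be covered, 74.3%, 57.0% and 53.7% within 1 kb, and 63.0%, 51.0% and 44.2% with the wider 50% of every list. Narrow later peaks cannot cover wide dome peaks, which bears on the H3K4me1 value. Joined peaks gave 55.2% and 53.5% for the last 2 marks, and placed chromosomes 49.2% for H3K27ac. The share of regions with a peak at all 4 stages was 32.0%, 2.89% and 12.5% with 50% covered, 54.8%, 16.9% and 19.0% within 1 kb, 54.2%, 15.9% and 18.4% joined, 54.6%, 15.2% and 16.9% on placed chromosomes, 39.1%, 13.5% and 14.1% for the wider 50%, and 65.9%, 22.7% and 26.0% with the dome and 48hpf lists only.

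The share of distal H3K4me1 peaks with H3K27ac, from dome to 48hpf, was 60.4%, 45.8%, 51.5% and 49.2% with 50% covered, 69.5%, 52.0%, 57.3% and 52.7% within 1 kb, 66.7%, 45.9%, 51.1% and 48.5% joined, and 62.7%, 45.4%, 47.9% and 46.2% for the wider 50%. It was 64.4%, 68.9%, 71.7% and 62.4% for lists of equal length, 46.0%, 32.4%, 26.4% and 35.1% for windows in danRer6 and 43.6%, 29.1%, 21.4% and 38.1% for windows in danRer7. With H3K4me3 peaks of the same stage only it was 62.1%, 46.6% and 51.9% at the first 3 stages, and on placed chromosomes 48.5%, 53.8% and 50.7% at the last 3. Dome had the highest share except with lists of equal length.

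The share of gained distal H3K27ac with H3K4me1 beforehand, for gains by 80% epiboly, 24hpf and 48hpf, was 8.01%, 18.0% and 32.4% within 1 kb, 4.88%, 13.5% and 27.5% for the wider 50%, 6.81%, 5.97% and 13.6% for lists of equal length, 5.10%, 9.13% and 19.4% for windows in danRer6 and 7.08%, 11.1% and 22.96% for windows in danRer7. With 50% covered it was 9.60% and 16.5% at the last 2 steps, and with H3K4me3 peaks of both stages only 6.48% at the first. It was highest for gains by 48hpf under each of these, and rose at every step except with lists of equal length.

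Among the 36 named entries, 1 read per position moved 5 fold changes, thinned reads 3, scaling 9, 0.1 RPM added 3 and 2 RPM added 26, and none changed direction. Over all values outside the main results, these entries included, 287 moved and 274 did not. The file scores that a stricter threshold needs are absent from the peak lists used here, so peak width took their place. The promoter signal of gene lists, with its wider window and larger pseudocount, was not run because no annotation of these builds was used, and leaving out replicates does not apply with 1 library per mark and stage. No paired analysis was possible because no result comes from a test and each group has 1 sample. Depth limits what can be said of single regions: random splits of the H3K4me1 library of 24hpf, with 4682378 reads, gave 1315 regions with a 4-fold difference.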

Other observations

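Of the tests in this part, the share of peaks holding an enriched window was planned before its values were seen, and all others were chosen after. Regions were also counted where both earlier stages stood at least 4-fold apart from both later ones. Steps after dome or after 24hpf were not counted in this way, so these numbers do not show where the largest step lay. H3K27ac was that much higher at dome and 80% epiboly at 684 regions and at 24hpf and 48hpf at 792, of 99556 tested. H3K4me1 was higher early at 314 regions and late at 643, of 107441, and H3K4me3 early at 224 and late at 282, of 57179. Both enhancer-associated marks shared 102 of the early regions and 94 of the late ones. H3K27ac regions that alternated, high at dome and 24hpf or at 80% epiboly and 48hpf alone, numbered 0 and 3, although all 4 of its files were of 1 kind.

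Few H3K27ac regions were present at the first and last stage alone. Peaks at dome and 48hpf but at neither stage between were found at 1.31% of regions, against 12.7% at 24hpf and 48hpf and 6.46% at dome and 80% epiboly. Of the 12109 regions acetylated at dome only, 10067 were distal, and of the 14209 acetylated at 48hpf only, 12560. H3K4me3 regions limited to 1 stage numbered 1325 at dome, 1880 at 80% epiboly, 1355 at 24hpf and 315 at 48hpf. Marks were unevenly spread over chromosomes. Chromosome 4 had the fewest H3K27ac peaks per Mb of the 25 chromosomes at every stage, 19.0 at dome and 24.3 at 48hpf against 28.9 and 38.0 over all, and also the fewest H3K4me1 peaks per Mb, 14.0 and 30.9 against 23.02 and 47.2. Chromosome 4 also held few reads for its 71.7 of 1323 Mb: 3.43% of placed H3K27ac reads at dome and 3.17% at 48hpf, and 3.39% and 3.29% for H3K4me1. Peaks per Mb were not corrected for this. Chromosome 23 had the most H3K4me1 peaks per Mb, 27.3 at dome and 57.7 at 48hpf.

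The number of H3K4me1 peaks was larger at 48hpf than at dome while enriched windows were fewer. Greater depth was argued against, since the 48hpf library had 0.727 times the distinct positions of dome, and so was the cutting of broad peaks, since a dome peak still overlapped at 48hpf held 1.25 peaks there and 44141 peaks (67.0%) lay outside every dome peak. A weaker enrichment admitted to the 48hpf list stays possible, but the share of peaks that held a window enriched at equal depth cannot decide it. That share was 29.7% at 48hpf, against 62.1% at dome, 42.4% at 80% epiboly and 39.2% at 24hpf. The peaks that held a window numbered 20000 at dome and 19539 at 48hpf, so the longer list by itself gives the lower share. The wider dome peaks also meet a window more easily. Marking of further distal sites may explain part of the number, since H3K4me1 over surroundings was 2.32 times higher at 48hpf than at dome where H3K27ac was present at 48hpf only. Both stay hypotheses, and the tests do not say how large each part is.

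Regions high in both H3K4 marks at 80% epiboly and 24hpf alone numbered 44, against 0.0325 for independent lists, none of them shared with H3K27ac, and 40 lay on unplaced sequences. H3K4 methylation at those stages alone was tried as an explanation at the 36 of them under 1 distinct read per 10 bp. There log2 of H3K4me3 over H3K4me1 at 80% epiboly had an SD of 0.31 (95% interval 0.24 to 0.35). It was 0.83 (0.51 to 0.99), pooled within each set, at the 9 early and 10 late regions picked by the same rule in both marks. The late ones were read at 24hpf, so the SDs come partly from different libraries. Short stretches may also reach 1 read per position, which narrows the ratio. The smaller SD therefore does not decide against methylation. Of 88 shared windows, 5 were left in danRer7. Reads matching sequence that danRer7 no longer holds are a possible source of the others, but no sequence was compared. Most of those lay on unplaced sequences, with 1 on chromosome 10, 2 on chromosome 11 and 1 on chromosome 23. Every library was mapped to danRer6, so lost sequence alone does not explain why these libraries were high and the rest were not. The 5 windows left were the ones on chromosome 3, where 100% remained, so lost sequence does not account for that region. For the chromosome 3 region, extra DNA in the 4 H3K4 libraries of 80% epiboly and 24hpf is a candidate source. In danRer7 with repeats kept, both antibodies gave it about the same RPM at 24hpf. H3K4me1 had 1.02 times as many as H3K4me3 (5024 and 4938), against 11.5 for H3K27ac. At 80% epiboly they differed more, with 2058 RPM for H3K4me1 and 887 for H3K4me3, against 2.29 for H3K27ac. Where such DNA would come from was not tested.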
